A study of Mus musculus with 6 samples.

How the data were processed

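The series holds whole-heart RNA sequencing of 6 mice, 3 per genotype, with groups and replicate numbers taken from the sample titles. The labels describe each sample as the heart of a male mouse of its own, so limma p-values of single genes measure the spread between animals. Per the labels' protocols, hearts were frozen, RNA was extracted with Trizol and libraries were made from polyadenylated RNA with a TruSeq kit. The design text calls the libraries stranded, whereas the kit named in the protocol does not mark strand, and the strand setting of the counting is not given in the sources used here. Genes that overlap on opposite strands therefore cannot be told apart with certainty.

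Per the submitters' processing notes, reads were aligned with TopHat (version 1.0.0) and expression and differences were computed with Cufflinks and Cuffdiff. FPKM values per gene and library, and a group FPKM per genotype, were deposited by the authors. Per the file headers, the authors' deposited table also gives a p-value and a q-value per gene, and the authors' deposited log2 fold change is cKO over fl/fl. The group FPKM lay within 1% of the mean of the 3 library values for 99.95% of 11813 genes. No FPKM is below 0.01, and 6563 genes are at 0.01 in every library, so 0 was replaced by 0.01 before deposit. Names of 27 rows had been turned into dates and were kept as unnamed rows, and 1 row with a failed value (Trip10) was left out. No row lies on the mitochondrial chromosome, so mitochondrially encoded transcripts were not analysed here. The submitters name mm10, but of 23265 rows whose symbol is in the GENCODE M21 annotation of mm10 only 2979 overlapped that gene's position there, so the build behind the coordinates is not settled. Coordinates are printed as the authors' files give them, and none was combined with the mm10 annotation.

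FPKM are not counts, so no count test was used and no interval from read numbers is given. Differences were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided) over genes with a mean FPKM of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes, so ratios of group means are given beside it. The 51 gene lists and the test were fixed before the data were examined, and 47 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which compares a list with no other genes. The preset treats the members of a list as nearly independent, so camera p-values under it do not measure the spread between animals. Named genes followed a rule fixed in advance, which took Ccnc and the kinase module, the 12 largest changes per direction among called genes with non-overlapping groups (leaving out rows with no symbol and symbols of predicted or small non-coding genes), up to 4 genes with the smallest p per called list or list with 3 called members, 5 genes per direction from the authors' deposited table, and markers quoted as levels. Of the genes quoted as levels, the clock genes, Dnm1l and Nppa were chosen after their values were seen.

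On simulated log-normal values for the same 12103 genes, with the real means and spreads and 200 genes changed, the test recovered 82% of genes changed by 1 and 96% of genes changed by 2 on the log2 scale, with 7 false calls among 185. With no gene changed it made 0 calls. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, so recovery of lower genes was not tested. Genes were simulated independently of each other, without the variation that genes share in the real libraries. No pair of libraries was a duplicate, and the closest pair differed by 0.252 (root mean square log2). Alternatives covered the pseudocount, the filter, scaling, the variance model, sample weights, the replicate number as a block and each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.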

Results

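Messenger RNA was measured by sequencing in whole hearts of 6 male mice aged 6 weeks, 3 with floxed cyclin C alleles alone (fl/fl) and 3 that also carried a Cre recombinase driven by the alpha myosin heavy chain promoter, which is active in heart muscle cells (cKO). Cyclin C is the cyclin of the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. The comparison asks which transcripts differ in the heart when the gene is deleted in cardiomyocytes. The fl/fl hearts carried no Cre, so the presence of Cre and the deletion differed together. Expression was given as FPKM for 24315 rows, and the number of reads per library is unknown. The steps between low values placed the depth of the other libraries at 0.885 to 1.1 times that of fl/fl 1 on the authors' FPKM scale. The sum of FPKM ran from 589196 in cKO 3 to 768960 in fl/fl 2. In each library the 10 most abundant genes held 14.4% to 16.5% of that sum in fl/fl and 11.4% to 12% in cKO. In a check of sex-linked transcripts 0 of the 6 libraries disagreed with their labels.

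Cyclin C itself (Ccnc) was lower in every cKO library than in every fl/fl library, at 5.35 ± 0.71 FPKM (SD, n = 3) against 8.97 ± 1.67 FPKM (SD, n = 3). The single values were 8.48, 7.6 and 10.8 FPKM in fl/fl 1 to 3 and 5.81, 5.7 and 4.53 FPKM in cKO 1 to 3. On the log2(FPKM + 1) scale this was a change of -0.65 (SE 0.15) that did not pass the threshold in limma (adjusted p = 0.144). A two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 allows. In the authors' deposited table the q-value of Ccnc was 0.161, and the gene was not called there either. The row covers chromosome 4, 21654847 to 21694358, a stretch that the files also assign to Tstd3, and a gene-level FPKM does not tell transcripts with and without the deleted part apart. None of the 5 other tested members of the kinase module passed the threshold, which does not show that they were unchanged. Adjusted over the module alone, Ccnc was the 1 member to fall and 0 rose. Cdk8 was at 9.07 ± 1.08 FPKM in fl/fl and 9.46 ± 1.05 FPKM in cKO, and Med13 at 7.18 ± 0.587 and 8.14 ± 0.268 FPKM (SD, n = 3 each). Med13 was higher in every cKO library than in every fl/fl library. Adjusted p-values over Cdk8, Cdk19, Med12, Med13 and Med13l ran from 0.527 to 0.985.

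In cKO hearts 71 of 12103 tested genes changed, 44 of them higher and 27 lower (limma, adjusted p under 0.05). The largest increase was in Nmrk2, a nicotinamide riboside kinase of the NAD salvage pathway, which rose from 5.07 ± 1.06 to 71.8 ± 13.3 FPKM (SD, n = 3), a ratio of 14.2 (adjusted p = 0.000165). Scgb1c1, a secretoglobin, rose from 27.9 ± 4.2 to 320.2 ± 38.4 FPKM, and Cpxm2, a carboxypeptidase-like protein, from 2.59 ± 0.614 to 31 ± 7.05 FPKM. Transcripts of skeletal and smooth muscle actin rose as well. Skeletal muscle alpha-actin (Acta1) went from 175 ± 59.5 to 1244 ± 279 FPKM and smooth muscle alpha-actin (Acta2) from 96.1 ± 9.42 to 548.5 ± 71.6 FPKM, with adjusted p-values of 0.00333 and 0.000212. Both share long stretches of sequence with the main cardiac actin, Actc1, so reads could be split among them. Actc1 read 8953 ± 621 FPKM in fl/fl and 10927 ± 417 FPKM in cKO. It was higher in each cKO library than in any fl/fl library but was not called. The myosin light chain Myl1 rose 3.59-fold, to 461.7 ± 11.5 FPKM. The files place Nmrk2 on 1 stretch with Atcay and Atcayos, and Scgb1c1 with Urah and C330022C24Rik, so reads of these rows may not be fully separable. The Nogo receptor Rtn4r rose 8.9-fold, the ketone body enzyme Bdh1 6.82-fold, the G protein subunit Gnb3 6.65-fold, Tmem116 4.76-fold, the water channel Aqp8 4.7-fold and Pcbd1 3.73-fold.

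Among the genes that fell, Bmp10, a bone morphogenetic protein on the fixed list of atrial markers, read 54.9, 27 and 21.6 FPKM in fl/fl 1 to 3 and 0.01, 0.0757 and 0.429 FPKM in cKO 1 to 3, where 0.01 is the lowest value in the file and stands in place of 0. As the number of reads is unknown, a value of 0.01 does not show that the transcript was absent. Hamp, which encodes hepcidin, read 52.5, 62.4 and 26.2 FPKM in fl/fl and 0.43, 0.47 and 1.37 FPKM in cKO. Their adjusted p-values were 0.000629 and 0.000815, and Hamp has a near-identical neighbour, Hamp2, with which it may share reads. Myoglobin (Mb), the oxygen-binding protein of muscle, fell from 18391 ± 2444 to 7592 ± 700 FPKM, 2.42-fold (adjusted p = 0.0367). Ryr2, the calcium release channel of the sarcoplasmic reticulum, fell from 113.8 ± 7.88 to 55 ± 3.47 FPKM (adjusted p = 0.00604). Ndrg4 fell 3.23-fold, Slc17a7 4.73-fold, the secreted Wnt-binding protein Sfrp5 5.53-fold, Mlana 5.61-fold, B3galt2 5.54-fold, Sbk2 3.15-fold and Ifltd1 3.9-fold. Tmem82 and AI507597 fell 2.97-fold and 2.96-fold, but the files place both at 1 locus, and their reads may not be separable. The same limit holds for Mb with Apol6, B3galt2 with Cdc73 and Slc17a7 with Mir7055. How much atrial tissue each sample held is left open below, and its part in these falls was not tested. Within cKO, Slc17a7, Mlana, Sfrp5, Sbk2, Tmem82 and Ifltd1 read highest in cKO 1, as did the atrial gene Myl7. Bmp10, Hamp, Ndrg4, B3galt2, Mb and AI507597 did not.

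**Figure D1:**
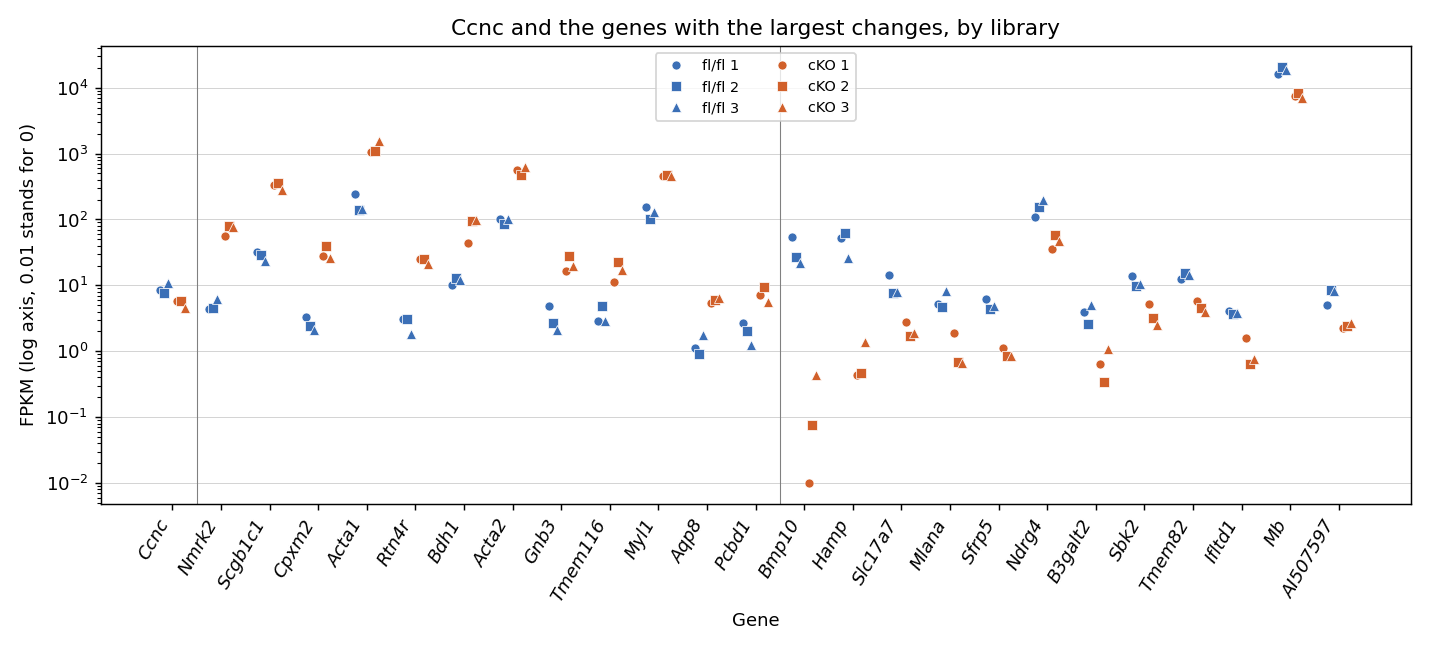
FPKM of Ccnc and, among called genes, the 12 with the largest increase and the 12 with the largest decrease (x axis), leaving out predicted and small non-coding genes, in each of the 6 libraries, on a log axis (y). Blue points are fl/fl and orange points cKO, with circles, squares and triangles for replicates 1, 2 and 3. The groups do not overlap for any gene shown, which was a condition of the choice for all but Ccnc. Bmp10 lies at the file's lowest value of 0.01 FPKM in cKO 1.

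The groups did not overlap for any of the 71 changed genes, which the threshold itself favours, so it adds no support to the calls. Over all tested genes the groups did not overlap for 20.4%, against 10% by chance. The count of changed genes was 18 without fl/fl 2, 33 without fl/fl 3, 33 without cKO 1, 13 without cKO 2 and 26 without cKO 3, and 50 without fl/fl 1. Acta1, Acta2, Bmp10, Cpxm2, Hamp, Myl1, Nmrk2, Rtn4r, Ryr2, Scgb1c1 and Sfrp5 were called in all 6 of those fits, and 20 of the 71 in none, among them B3galt2, Cacna1h and Slc36a2. Gnb3 lost its call without fl/fl 2, Aqp8 without cKO 2, and Bdh1 and Tmem82 without each of these 2 libraries. Mb and Slc17a7 were called in 2 of the fits, and Tmem116, Pcbd1, Mlana, Ndrg4, Sbk2, Ifltd1 and AI507597 in 1. Replicate 3 of both genotypes differed from the others in clock genes. Arntl stood at 8.84 FPKM in fl/fl 3 and 13.7 FPKM in cKO 3 against at most 1.36 FPKM elsewhere, and Dbp at 22.8 and 8.91 FPKM against at least 93.6 FPKM. With that division as a term 123 genes were called, and within replicates 1 and 2 alone 13 genes. Replicate 3 alone leaves 1 library per genotype and no test.

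Contractile and calcium genes were examined through lists fixed before the data were examined. Of the 10 splits of the samples into 3 and 3, 6 gave at least 14 list calls, the real split included. The number of list calls therefore does not set the genotypes apart, a limit on all list calls below. Of 14 ventricular cardiomyocyte markers, 2 fell over all genes tested (Mb and Ryr2) and 8 fell adjusted over the list alone. Signs were negative for 10 and positive for 4. The list was lower in camera (median log2 change -0.58, adjusted p = 4.51e-05; adjusted p = 0.857 with an estimated correlation). With quantile normalization this median was -0.222, and the log2 change of Mb -0.654 against -1.27. The ventricular myosin light chain Myl2 read 20206 ± 3863 FPKM in fl/fl and 9321 ± 796 FPKM in cKO (adjusted p = 0.0873), and cardiac troponin T (Tnnt2) 8430 ± 1516 and 4614 ± 384 FPKM (adjusted p = 0.127). Of 28 sarcomere and Z disc genes, 0 passed over all genes tested, while 8 fell and 2 rose adjusted over the list alone (camera median -0.17, and -0.063 with quantile normalization; adjusted p = 0.00233; adjusted p = 0.857 with an estimated correlation). That call also ended with quantile normalization, with no filter, without cKO 3 and within replicates 1 and 2. Of these sarcomere and Z disc genes 19 had a negative and 9 a positive sign. Tnni3 stood at 8598 ± 1977 and 4665 ± 624 FPKM and Csrp3 at 2216 ± 265.5 and 1496 ± 56.3 FPKM in fl/fl and cKO, without passing over all genes. In the calcium handling list Ryr2 fell and the T-type calcium channel Cacna1h rose 2.01-fold over all genes tested, with 5 falling and 2 rising adjusted over the list alone. The list lay lower in camera (median -0.12, adjusted p = 0.0414), a call absent with an estimated correlation (adjusted p = 0.857) and in 9 of its 18 other settings, among them quantile normalization (median -0.0738), the fits without fl/fl 3, cKO 2 or cKO 3 and replicates 1 and 2 alone. Without fl/fl 1 the median was -0.197. Phospholamban (Pln) read 4598 ± 461 and 3068 ± 129 FPKM, and Hrc 527.9 ± 81.5 and 342.5 ± 30.2 FPKM, neither passing over all genes. Of 32 genes of the hypertrophy and fetal program, Nmrk2, Acta1 and Acta2 rose over all genes, and 7 rose and 5 fell adjusted over the list alone. Its members include the atrial genes Myl7, Myl4 and Mybphl, which read lower in each cKO library than in any fl/fl library and are taken up below. The list as a whole was not called (camera adjusted p = 0.0558). The natriuretic peptide Nppa read 3715, 2436 and 1827 FPKM in fl/fl 1 to 3 and 3231, 1040 and 2178 FPKM in cKO 1 to 3. Acta2 was the only smooth muscle and pericyte marker of 13 to pass over all genes, and 3 rose and 2 fell adjusted over the list alone. The list had 9 positive and 4 negative signs and was not called by camera (adjusted p = 0.0554).

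Genes of oxidative metabolism lay slightly lower as sets in cKO, with no member passing over all genes tested. Other splits of the samples called as many lists, so these calls alone do not tie the sets to genotype. Ventricular cardiomyocyte markers lay lower as well (median -0.58), while endothelial and fibroblast markers lay higher (medians 0.27 and 0.22). For complex I of the respiratory chain 36 of 37 members had a negative log2 change (median -0.26; camera adjusted p = 1.64e-08), and for complexes II to V 39 of 39 (median -0.25; camera adjusted p = 1.48e-08). Both calls were absent with an estimated correlation, which was 0.85 for complex I and 0.89 for complexes II to V (camera adjusted p = 0.857 for each). Library fl/fl 2 had the highest FPKM for 34 of the 37 and 37 of the 39 members. Without it the medians were -0.12 and -0.127, and with quantile normalization -0.102 and -0.056. The medians of the next 2 lists shrank too, fatty acid genes to -0.16 without fl/fl 2 and -0.163 with quantile normalization, and tricarboxylic acid cycle genes to -0.103 with quantile normalization. Ndufa13 stood at 421.6 ± 74.2 and 292.2 ± 20.8 FPKM, and Uqcrc2 at 870.2 ± 69 and 682.5 ± 44.4 FPKM in fl/fl and cKO, and Ndufs5 had the opposite sign at 142.1 ± 27 and 192.2 ± 14.4 FPKM. Of 38 genes of fatty acid uptake and oxidation, 32 had a negative and 6 a positive sign (median -0.27; camera adjusted p = 0.000114; adjusted p = 0.857 with an estimated correlation). Acadm, a medium-chain acyl-CoA dehydrogenase, read 972.2 ± 152 and 658.3 ± 77.4 FPKM. Ucp3, a mitochondrial carrier, was the 1 member to rise adjusted over the list alone, at 37.9 ± 5.41 and 63.1 ± 10.3 FPKM. Of 18 tricarboxylic acid cycle genes 16 were negative (median -0.23; camera adjusted p = 0.000401; adjusted p = 0.857 with an estimated correlation), and Me3, at 29.5 ± 4.07 and 18.9 ± 2.15 FPKM, fell adjusted over the list alone. Cyclin C has been studied for a role in mitochondrial division. None of 21 tested genes of mitochondrial fission and fusion passed (camera adjusted p = 0.117), and the fission factor Dnm1l read 51.2, 49.4 and 55.7 FPKM in fl/fl and 51.4, 48.8 and 48.6 FPKM in cKO.

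Interferon-response, stromal and endothelial genes lay higher as sets in cKO, again with no member passing over all genes tested. The limit from other splits of the samples holds for these calls too. In whole-heart FPKM, a relative measure, a change within cells and a change in the share of cell types cannot be told apart. This holds for the lower oxidative and cardiomyocyte sets too, and neither was tested. Of 34 interferon-response genes 31 were positive and 6 rose adjusted over the list alone (median 0.36; camera adjusted p = 9.91e-10; adjusted p = 0.743 with an estimated correlation). The guanylate-binding protein Gbp6 read 5 ± 0.481 FPKM in fl/fl and 10.1 ± 2.43 FPKM in cKO, and Xaf1 2.53 ± 0.39 and 4.9 ± 0.613 FPKM. For extracellular matrix and fibrosis 31 of 36 genes were positive (median 0.27; camera adjusted p = 0.000197; adjusted p = 0.857 with an estimated correlation), and the call ended without fl/fl 2 (median 0.109). The median was 0.138 without cKO 3 and 0.131 with array weights. Col8a1 read 10.1 ± 1.6 and 15.5 ± 1.49 FPKM, and biglycan (Bgn) 152.1 ± 14.3 and 200.4 ± 15.1 FPKM. All 18 endothelial markers were positive (median 0.27; camera adjusted p = 4.74e-06), as were 15 of 16 fibroblast markers (median 0.22; camera adjusted p = 0.000958) and 16 of 18 Notch pathway genes (median 0.15; camera adjusted p = 0.00822). Each of these 3 calls was absent with an estimated correlation (adjusted p = 0.743). The Notch call also ended without cKO 3 (median 0.099). The Notch median was 0.232 without cKO 1, 0.0987 with a pseudocount of 5 and 0.295 at a mean FPKM of at least 5, and the endothelial median was 0.17 within replicates 1 and 2.

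Markers of tissue next to the ventricles differed between single libraries. The atrial cardiomyocyte list was lower in cKO (median -1.34 over 13 genes; camera adjusted p = 2.07e-05; adjusted p = 0.743 with an estimated correlation). Bmp10 fell and Myl1 rose over all genes, and 8 fell adjusted over the list alone. The atrial myosin light chain Myl7 read 1116, 808 and 681.6 FPKM in fl/fl 1 to 3, and 323.5, 57.5 and 64 FPKM in cKO 1 to 3 (adjusted p = 0.0997). Sarcolipin (Sln), also abundant in atria, read 529.6, 347.4 and 270.9 FPKM in fl/fl and 268.2, 34.2 and 33.6 FPKM in cKO. The adipocyte list was lower (median -1.49 over 13 genes; camera adjusted p = 0.00233; adjusted p = 0.857 with an estimated correlation), a call that ended without fl/fl 1 (median -0.45) and with a mean FPKM of at least 5 (-0.95). Its median was -2.34 with a pseudocount of 0.1 and -0.768 with one of 5. Adiponectin (Adipoq) stood at 56.4 FPKM in fl/fl 1 and at most 3.16 FPKM elsewhere, and the thymocyte gene Rag1 at 14.6 FPKM in fl/fl 1 and at most 0.519 FPKM elsewhere. In the adipocyte list Slc36a2 fell 2.04-fold over all genes, and 2 fell and 1 rose adjusted over the list alone, the last being Thrsp at 57.3 ± 33.1 FPKM in fl/fl and 156.9 ± 19.9 FPKM in cKO. The lung gene Scgb1a1 read 3.06 FPKM in fl/fl 1 and 14.7 FPKM in fl/fl 2, and at most 0.323 FPKM in the other 4 libraries.

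**Figure D2:**
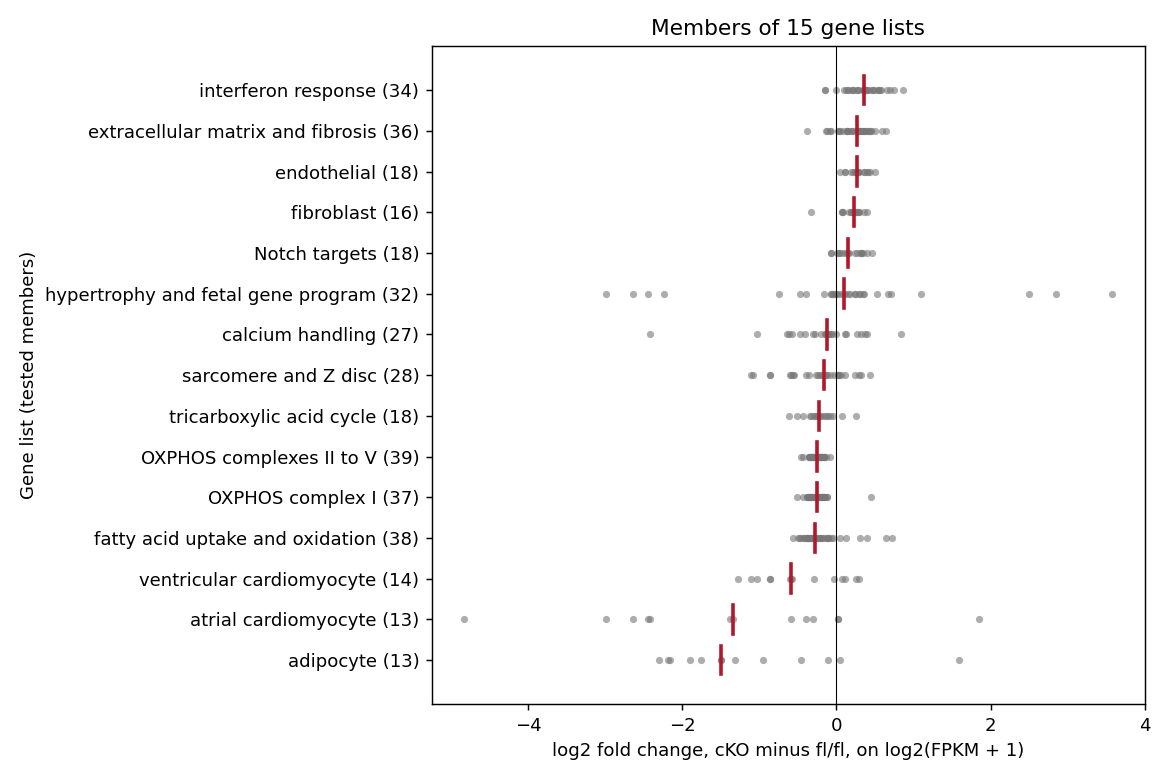
Log2 fold change, cKO minus fl/fl on log2(FPKM + 1) (x axis), of each tested member (grey points) of the 14 lists called by camera and of the hypertrophy and fetal program list (y axis, with the number of tested members). Red bars mark the medians, which run from -1.49 for adipocyte markers to 0.36 for interferon response.

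The 33 other lists with at least 5 tested members were not called by camera. Among them were the Mediator core (camera adjusted p = 0.694), apoptosis (0.694), cell cycle (0.694), p53 targets (0.621), the oxidative stress response (0.117), the response to mitochondrial stress through ATF4 (0.526), ribosomal proteins (0.312), macrophage markers (0.283) and lymphocyte markers (0.171). Across all 47 lists the estimated correlation left 0 calls in camera, with the lowest adjusted p at 0.743. The directional fry test also left 0, with the lowest adjusted p at 0.135, while its mixed form, which asks whether members change in either direction, called 14. These were not the same 14 as in camera. Both called the sarcomere, calcium handling, interferon, atrial and ventricular lists. Mixed fry did not call complex I (adjusted p = 0.159), complexes II to V (0.182), endothelial (0.0657) or fibroblast markers (0.0787), among others. It did call p53 targets (0.00216), glycolysis (0.00743), the hypertrophy list (0.000818) and the Mediator kinase module, which holds Ccnc (0.0333), among others.

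The authors' deposited table called 474 of 12587 tested genes at their false discovery rate of 0.05, 212 higher and 262 lower in cKO. Of these, 63 were among the 71 limma calls with the same sign. Both sets of calls rest on the same 6 libraries and FPKM values, so their overlap does not measure independent agreement. Of 441 authors' calls among the genes tested here, 340 had an unadjusted limma p under 0.05. By the authors' deposited table the largest increases among its called genes with both group values of at least 1 FPKM were in Nmrk2, Cpxm2, Scgb1c1, Rtn4r and Acta1. Among its called genes with both group values of at least 1 FPKM, the largest decreases were in the adipocyte genes Cfd and Car3, in Hp and Cyp2e1 and in the T cell factor Tcf7, with log2 changes of -4.19, -4.06, -3.73, -3.12 and -2.69. All 5 were at least 2-fold higher in fl/fl 1 than in any other library. Cfd read 295.5 FPKM there against 4.37 to 10.9 FPKM in the other 5 libraries, and none of the 5 was called by limma (adjusted p from 0.32 to 0.775). Without fl/fl 1, Tcf7 was higher in cKO, at a log2 change of 0.57. Of the 262 lower calls in the authors' deposited table, 72 were at least 2-fold higher in fl/fl 1 than in every other library. The 8 limma calls the authors' deposited table did not make included Bmp10, Hamp, Mlana, B3galt2 and AI507597, whose q-values there ran from 0.0559 to 0.221. The shared count was 43 without fl/fl 1, 15 without fl/fl 2, 30 without fl/fl 3, 29 without cKO 1, 10 without cKO 2 and 23 without cKO 3.

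**Figure D3:**
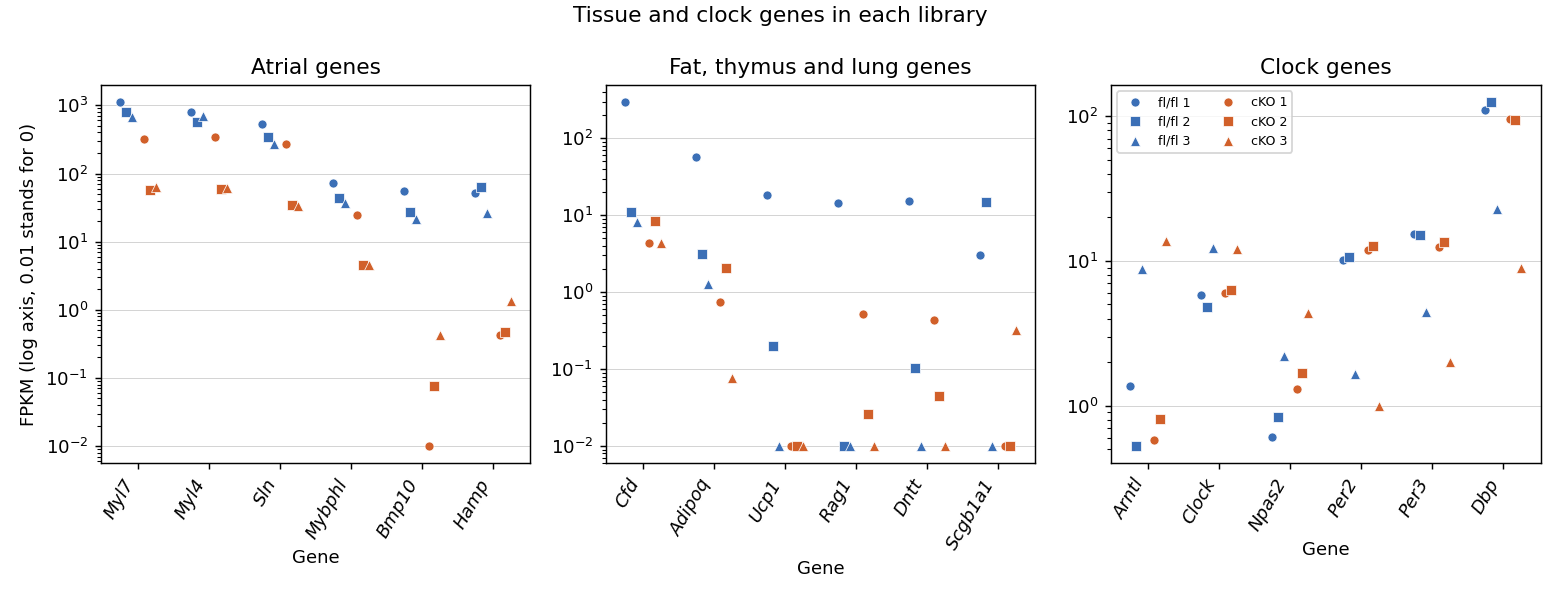
FPKM on a log axis (y) of atrial genes, of fat, thymus and lung genes and of clock genes (x axis) in each of the 6 libraries, with colours for genotype and symbols for replicate as given in the legend. Atrial genes are lowest in cKO 2 and cKO 3, Bmp10 and Hamp are low in all 3 cKO libraries, fat and thymus genes peak in fl/fl 1, and Arntl is highest in fl/fl 3 and cKO 3 (8.84 and 13.7 FPKM).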

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

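Except for 2, the alternatives were fixed before the data were examined. The fit with replicate 3 against the others as a term and the fit on replicates 1 and 2 only were chosen after seeing the data. The 71 genes (44 higher, 27 lower), the 14 lists and the 63 genes shared with the authors' deposited table moved by less than 1.5 times with a pseudocount of 0.1 or 5, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, robust eBayes and array weights. With no filter, which tested 17751 genes, 14 genes were called (10 higher, 4 lower) and 12 shared. Without the trend 38 were called (23 higher, 15 lower) and 32 shared. With replicate 3 as a term the counts were 123 (69 higher, 54 lower) and 105 shared, and on replicates 1 and 2 only 13 (10 higher, 3 lower) and 9 shared. The cause of these shifts was not tested, and the fit on replicates 1 and 2 only also had fewer samples. With the replicate number as a block the counts were 213 (117 higher, 96 lower), 13 lists and 181 shared, and Ccnc kept its change of -0.65 (adjusted p = 0.0895). Deviations of same-numbered libraries correlated at 0.089, 0.271 and 0.429, and cKO 1 correlated best with fl/fl 2 (0.152). With pair 1 under 0.1 the numbers were not taken to pair the samples, although replicate 3 of both genotypes shared a clock gene pattern. In the labels' sample codes, replicate 3 of both genotypes also carries lower numbers than the other libraries. What these numbers count is not given, so a shared set for replicate 3 stays open. Leaving out 1 library gave 13 to 50 genes (9 to 29 higher, 4 to 21 lower), 11 to 18 lists, 10 to 43 shared and a Ccnc change of -0.75 to -0.52. Ccnc kept its direction and stayed short of the threshold in all alternatives, with adjusted p from 0.0895 to 0.404. The lists fell to 0 with an estimated correlation and 0 with directional fry. Cdk19, at a log2 change of 0.0057, turned to -0.027 with quantile normalization, -0.0033 with array weights and -0.048 on replicates 1 and 2 only, where Cdk8 read -0.033 and Med12 0.030. Without single libraries Cdk19 ran from -0.056 to 0.082, Cdk8 from -0.011 to 0.14, Med12 from -0.18 to 0.094 and Tcf7 from -1.54 to 0.57, the last without fl/fl 1. No symbol occurred in more than 1 row, so summing rows of a symbol was not run. Absolute depth is unknown and limits what can be said of genes near 0.01 FPKM.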

Other observations

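Genes named in this paragraph were picked after their values were seen. Further muscle genes among the 71 were the calcium-binding protein sorcin (Sri), which rose from 23.4, 23.9 and 21.4 FPKM in fl/fl 1 to 3 to 39.7, 43.4 and 43.5 FPKM in cKO 1 to 3 (limma adjusted p = 0.0099), the tropomyosin Tpm2, 2.52-fold higher, and the myosin light chain Myl9, 2.22-fold higher. The small heat shock protein Hspb6 fell 1.81-fold (limma adjusted p = 0.0456) and the homeodomain protein Hopx 1.81-fold (limma adjusted p = 0.0242). Among other genes of the 71, Abat rose 2.8-fold, Shmt1 2.34-fold, Aldh1b1 2.04-fold and Fah 1.74-fold, while the fixed list of amino acid and ketone catabolism had 16 of 24 negative signs and was not called (camera adjusted p = 0.12). Sri and Abat lost their calls without cKO 2, Tpm2 and Fah without each library in turn, and the others in at least 4 of the 6 fits that left out 1 library.

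For the 3 patterns below, all tests were chosen after the result was seen. The first is the lower level of atrial genes in cKO. Less atrial tissue in the cKO samples would lower Myl7, Myl4, Sln and Mybphl by 1 common share in each library. Their log2 ratios to the fl/fl mean had an SD of at most 0.375 within a cKO library, around 50% of fl/fl in cKO 1, 8.23% in cKO 2 and 8.47% in cKO 3, but they were picked because they moved together. Other tested members of the list lay elsewhere, Dkk3 at 55%, 42.8% and 21.9% of its fl/fl mean in cKO 1 to 3, Stard10 at 63.1%, 28.8% and 26.7%, Nppa, the most abundant, at 121%, 39.1% and 81.9%, Pam at 124%, 95.6% and 85.8%, Kcnk3 at 92.2% to 111% and Myl1 at 354% to 369%, so a difference in how much atrium was taken may underlie the 4 genes but was not decided. The share of those 4 genes did not account for Bmp10 and Hamp, which lay below that common share in each cKO library, by at least 1.54 log2 units (-1.543 at the closest). Hamp stood at 0.914%, 1% and 2.91% of its fl/fl mean in cKO 1 to 3. A lower level in cKO cells and a loss of the part of the atrium that makes Bmp10 and Hamp stay open, and neither was tested.

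The second pattern is the adipocyte and thymocyte genes among the authors' lower genes. Of 20 detected markers of fat, lung and thymus, 13 were at least 2-fold higher in fl/fl 1 than in every other library, and 8 of these 13 were lower calls in the authors' deposited table, which is consistent with fat and thymus tissue in the fl/fl 1 sample. In fl/fl 1 the fat gene Cfd read 295.5 FPKM and the thymus gene Dntt 15.2 FPKM. Fabp4, the most abundant member, was not raised there (1800 FPKM against 1807 in fl/fl 2 and 1794 in cKO 3). However, Fabp4 is also on the fixed endothelial list, so its level need not follow fat. Thrsp was higher in all cKO libraries (144.8 to 179.8 against 94.2 FPKM in fl/fl 1). Lower expression in cKO of the genes themselves was not decided. Without fl/fl 1 the median log2 ratio of cKO over fl/fl 2 and 3 was -0.734 over the 13 genes, and many values lay near 0.01 FPKM. Its standard error of 0.531 is over genes from the same libraries, so it does not measure the spread between animals.

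The third pattern is replicate 3 of both genotypes. Of 19 tested clock genes 17 moved with the same sign in fl/fl 3 and cKO 3, with Arntl, Clock and Npas2 up and Per1, Per2, Per3, Dbp, Nr1d1 and Nr1d2 down, so another time of day at collection is a candidate explanation, and a count from the genes that revealed the division cannot decide it. A batch with no link to time of day, as the whole cause, would leave the clock list no further apart than others, but its median absolute difference of 1.01 log2 units exceeded the largest that 100% of 10000 random lists of its size reached over the 9 possible divisions into 1 library per genotype and the rest (at most 0.317). Random lists lack the joint variation of real ones, and 7 other fixed lists also lay above 0.317 on this division. Among them were adipocyte markers (0.912, 0 of 13 passing), glucocorticoid targets (0.659, 7 of 22), immediate early genes (0.637, 4 of 20) and extracellular matrix (0.369, 4 of 36). Of the clock genes 13 of 19 passed, with Arntl at 2.75 (SE 0.239) and Dbp at -2.8 (SE 0.195). The division was found in these same genes, so neither their passing nor the random lists decide against a batch. In a fit with both terms 179 genes differed between replicate 3 and the others, so a batch, alone or beside a clock difference, stays open. The numbers in the sample codes of replicate 3 are also lower than in the other codes. The genotypes are balanced over this division.

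Other splits of the samples were planned. The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For single genes 1 of the 10, the real one, gave as many as 71 calls, and the highest of the others gave 0. For the fixed lists 6 of the 10 splits gave at least 14 calls, and the highest of the others gave 24. That split set fl/fl 1, cKO 1 and cKO 3 against the rest and called 0 genes. The number of list calls therefore does not tell the genotypes from other groupings of these samples.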
